A study of Zea mays with 6 samples.

How the data were processed

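RNA was measured in tassel meristems of maize, dissected at a length of 1 mm from B73 plants (WT, n = 3 libraries) and from plants of the tassel-less1 (tls1) mutant (n = 3 libraries). Per the labels' protocols, the libraries were enriched for poly-A RNA and sequenced as paired reads. Adapters were trimmed with cutadapt and reads aligned with STAR, per the submitters' processing notes. Their versions, the counting program, its strand setting and the genome build are not given in the sources used here, so antisense and overlapping genes, and near-identical copies of a gene, cannot be told apart with certainty in these values. The authors deposited a table of raw read counts, not normalized, for 45953 features in the 6 libraries. The counted reads of a library summed to between 72498318 and 77619452, and a count of 3 in a library corresponded to between 0.0387 and 0.0414 CPM, the library-size scaled unit used here for levels. Such floors cover counting error only.

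The table held 43789 nuclear gene identifiers, 1645 non-coding RNA identifiers, 208 mitochondrial genes, 157 plastid genes and 154 microRNA genes. The reference table of gene names used here (assembly Zm-B73-REFERENCE-NAM-5.0) matched all 208 mitochondrial and 157 plastid genes by locus tag and 153 of the 154 microRNA genes by synonym. It matched 0 of the nuclear and 0 of the non-coding identifiers, so nuclear genes are given by identifier only. All 34 gene lists fixed before the data were examined therefore had 0 members that could be found. The mutated gene, knotted1, the rte boron efflux genes and those lists are not analysed here. Groups of organellar genes and of non-coding RNA were defined in their place from the symbols, after the identifiers had been seen and before any group was tested. The 8 groups with at least 5 tested members were tested. The rule for naming genes, set before the data were examined, took the mutated gene, knotted1 and the rte genes, the largest rises and falls among called genes with a name, and the leading members of each list. It could name no nuclear gene. Of the 4 nuclear identifiers printed, 1 was the gene called by edgeR without the replicate block and the others had the lowest p of edgeR with the block in their direction. They were chosen after their values were seen.

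Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test on the counts with TMM normalization, the filterByExpr filter, genotype as the only factor and Benjamini-Hochberg adjustment over the 23349 genes that passed the filter. Calls were made at an adjusted p under 0.05. Values are given as CPM, mean ± SD, and log2 fold changes as tls1 over WT with their standard error (SE). Groups were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry beside it. Shares of reads were compared by 2-sided exact permutation tests, for which 0.1 is the smallest p that 3 against 3 libraries allow. These tests, also used for depth, treat the libraries as exchangeable and ignore the replicate numbers. Python 3.11.15 with scipy 1.17.1 was used for permutation tests.

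The replicate numbers are shared by the genotypes, and the labels do not say what a number stands for. Deviations from the genotype means were correlated across genes between WT and tls1 libraries of the same number, at 0.409 for number 1, 0.594 for number 2 and 0.653 for number 3. Between libraries of different numbers the correlations lay between -0.479 and -0.102. Deviations cancel within a genotype, so positive values for the same number force negative ones between numbers, and the latter are no separate evidence. The numbers were therefore taken to pair the libraries, on the evidence of the data alone, and a fit with the number as a replicate block is given beside results that it changes. Nothing in the labels says whether the libraries came from separate plants, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries agreed within sampling noise: the mean chi-square per gene was at least 46.2 in every pair. It was 46.2 for number 2 and 48.7 for number 3, but 134.3 for number 1. Between libraries of different numbers it lay between 51.3 and 146.2, so by this measure the libraries of number 1 were not alike.

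Alternatives chosen before the data were examined were RLE and upper quartile factors, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, the replicate block, leaving out each library and removing the 10 most abundant genes. Alternatives added after seeing the data were DESeq2 with the block, robust empirical Bayes, the block without each pair, and leaving out genes of the blocks in which a replicate pair stood apart. The fits were tested on simulated counts for the 23349 genes, in which 100 genes were changed 2-fold (log2 of 1) and 100 by a log2 of 2. Without the block, 49% and 71% of these were called, with 15 false calls. With the block, 68% and 88% were called, with 32 false calls, so the simulated lists held more false calls than the threshold of 0.05 aims at. Simulated counts were drawn independently for each library, with differences between replicate numbers only in the fit with the block. The real libraries had further structure, so these rates need not hold for them.

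For the position of genes, the row order of the deposited table was used. The 153 microRNA genes placed by the reference table served as landmarks: all 142 neighbouring pairs on 1 chromosome were in increasing order, with 10 changes of chromosome. Windows of 100 consecutive tested nuclear genes were compared with 10000 random placements. No coordinates are given, because the sources used here do not state the build of the counts.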

Results

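Poly-A RNA was profiled in 1 mm tassel meristems, the tissue that forms the male inflorescence of maize, from the inbred line B73 and from the tls1 mutant, which the labels describe as boron deficient. Plants were grown with fertilizer at 238 ppm nitrogen and 0.08 ppm boron, and per the series' design the meristems were taken before defects in form appeared. The design compared 3 WT with 3 tls1 libraries, to ask which transcripts differ at that stage. Counted reads numbered 77619452, 72498318 and 74815847 in WT libraries 1, 2 and 3 and 74486753, 73471188 and 74733984 in tls1 libraries 1, 2 and 3. The mean depth did not differ detectably between genotypes (exact permutation p = 0.7, 2-sided, smallest possible 0.1).

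In pairs 2 and 3, the WT and tls1 libraries of 1 replicate number were more alike than any 2 libraries of 1 genotype, and in pair 1 they were not. Over the 23349 tested genes, the correlation of log2 CPM was 0.983 between WT 2 and tls1 2, 0.983 between WT 3 and tls1 3 and 0.970 between WT 1 and tls1 1. Within a genotype it ran from 0.969 to 0.974 in WT and from 0.964 to 0.970 in tls1. The first principal component held 39.0% of the variance and placed WT 1, WT 3 and tls1 3 on one side and WT 2, tls1 1 and tls1 2 on the other. The second and the third held 24.9% and 21.4%. Within each of the 3 pairs, tls1 had a higher score than WT on the first and the second component and a lower score on the third.

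**Figure D1:**
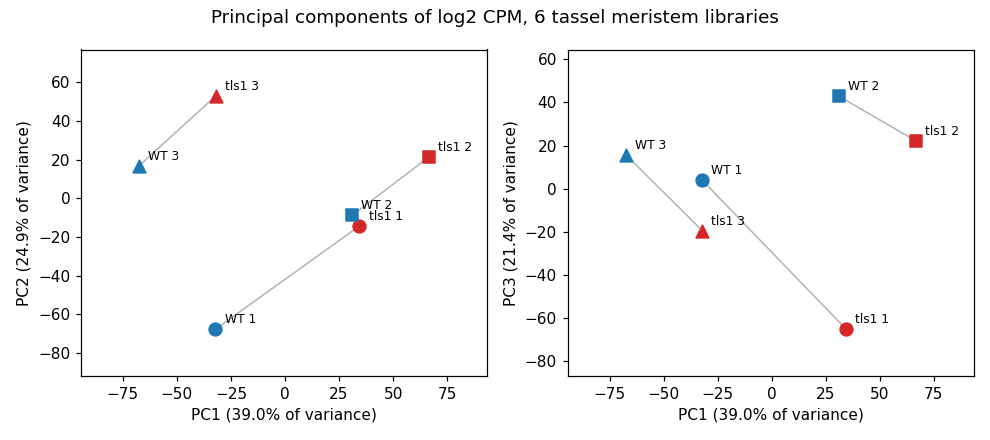
Principal component scores of log2 CPM for the 6 libraries, with the first component (39.0% of the variance) on the horizontal axes and the second (24.9%) or the third (21.4%) on the vertical axes. Blue points are WT, red points tls1, marker shapes and grey lines join libraries of the same replicate number, and within each pair tls1 lies to the right of WT, while the genotypes overlap on the first component.

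Transcripts of 1 nuclear gene, Zm00001d005813, rose in tls1. Its level was 7.18 ± 0.94 CPM in WT and 28.1 ± 0.93 CPM in tls1 (SD, n = 3 each), a log2 fold change of 1.97 ± 0.11 (SE, edgeR adjusted p = 0.0252), and it was higher in 3 of 3 tls1 libraries than in any WT library. The call was lost in 5 of the 6 fits that left out 1 library, with an edgeR adjusted p for Zm00001d005813 of 0.156 without WT 1, 0.298 without WT 3, 0.0678 without tls1 1, 0.0712 without tls1 2 and 0.0840 without tls1 3. A second gene, Zm00001d048841, had 9.91 ± 5.52 CPM in WT and 199.4 ± 70.6 CPM in tls1 (SD, n = 3 each), with a log2 fold change of 4.33 ± 0.54 (SE, edgeR adjusted p = 0.0879). With the replicate block its log2 fold change was 4.43 ± 0.16 (SE, edgeR adjusted p = 0.0070), and it then passed the threshold. Without the block, edgeR called no gene lower, while DESeq2 called 512 lower, among them the next 2 genes. Zm00001d012398 had 41.1 ± 5.90 CPM in WT and 23.7 ± 3.93 CPM in tls1, a log2 fold change of -0.80 ± 0.16 (SE, edgeR adjusted p = 0.130, and 0.0229 with the replicate block). Zm00001d037717 had 84.7 ± 21.5 CPM in WT and 46.6 ± 16.8 CPM in tls1, a log2 fold change of -0.86 ± 0.28 (SE, edgeR adjusted p = 0.221). With the replicate block its log2 fold change was -0.89 ± 0.07 (SE, edgeR adjusted p = 0.0229).

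**Figure D2:**
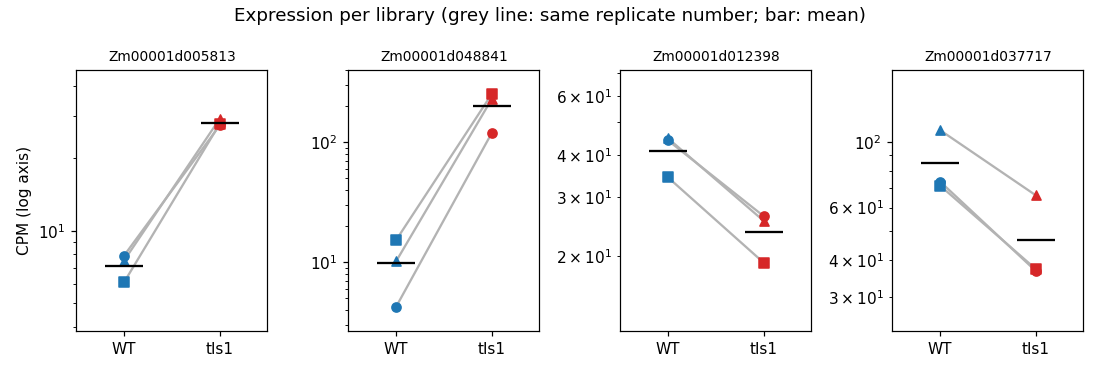
Expression in CPM, on a log axis, of the 4 nuclear genes given by identifier, in WT (blue) and tls1 (red) libraries. Grey lines join libraries of the same replicate number and black bars are means over 3 libraries, which for Zm00001d005813 are 7.18 CPM in WT and 28.1 CPM in tls1.

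Across all tested genes, edgeR without the block called 1 gene higher and 0 lower in tls1, while 1711 genes were higher and 2153 lower at an unadjusted p under 0.05. DESeq2 called 686 higher and 512 lower, and limma-voom 2 higher and 0 lower. All 3 tls1 libraries lay above all WT libraries in 2300 genes and below them in 2974, together 22.6% of the tested genes, where chance gives 10% for exchangeable libraries. These libraries were not exchangeable: the split of WT 1, WT 3 and tls1 3 from the rest, which keeps pairs 2 and 3 whole, left 25.6% of the genes without overlap and had 4579 genes at an unadjusted p under 0.05. The other 3 splits that part all 3 pairs, as genotype does, left 4.81%, 6.61% and 4.16%. The edgeR count depended on single libraries: 0 genes were called higher without WT 1, WT 3, tls1 2 or tls1 3, 2 without tls1 1, neither of them Zm00001d005813, and 9 without WT 2, and 1 gene was called lower without tls1 2.

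With the replicate block, edgeR called 115 genes higher and 47 lower in tls1, all of them nuclear. At an unadjusted p under 0.05 the balance was the other way, with 2141 genes higher and 2490 lower. Among the called genes, the rises were the larger changes: their median log2 fold change was 2.43, and 96 of the 115 exceeded 2-fold. Among the 47 genes called lower, the median size of the log2 fold change was 0.70, and 13 exceeded 2-fold. Of these 162 genes, 146 were also called by DESeq2 without the block, all 146 in the same direction. Both fits used the same counts, so this is no independent support. The biological coefficient of variation was 0.272 without the block and 0.165 with it. The blocked counts depended on single pairs: 301 higher and 132 lower were called without pair 1, 122 and 37 without pair 2, and 43 and 9 without pair 3.

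**Figure D3:**
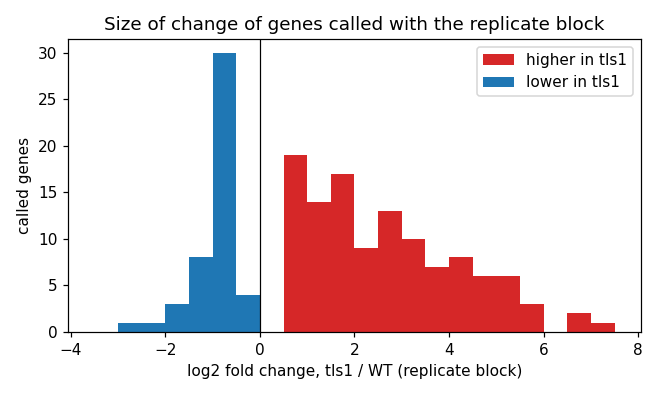
Number of genes called by edgeR with the replicate block, by log2 fold change of tls1 over WT in bins of 0.5. Red bars are the 115 genes called higher, with a median of 2.43, and blue bars the 47 called lower, with a median size of 0.70.

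Mitochondrial genes took 0.236% ± 0.072 of the counted reads in WT and 0.232% ± 0.091 in tls1 (SD, n = 3 each, exact permutation p = 0.9). Of 57 mitochondrial genes tested, 0 were called by edgeR with or without the block, and their median log2 fold change was -0.04. The SE of their log2 fold changes without the block ran from 0.26 for rrn5 to 1.05 for rpl23-ct, so large changes could have been missed. The pairs went opposite ways: summed over mitochondrial genes, 3209 CPM in WT 1 stood against 1336 in tls1 1, but 1880 in WT 2 against 3127 in tls1 2 and 2036 in WT 3 against 2441 in tls1 3. Most of each sum was ribosomal RNA. In WT 1, rrn26 had 2425 CPM and rrn18 598 CPM, and in tls1 1 they had 1013 and 257 CPM. For the tested respiratory chain and ATP synthase genes, the sum was 80.9 CPM in WT 1 against 28.8 in tls1 1. It was 45.3 in WT 2 against 75.5 in tls1 2, and 45.5 in WT 3 against 60.4 in tls1 3. Sums over the mitochondrial ribosomal protein genes and the open reading frames of unnamed function had the same direction within each pair. The pattern was therefore not confined to ribosomal RNA. The 7 tested genes of the respiratory chain and ATP synthase had a median of -0.02 (camera adjusted p = 0.891). Among them, cox1, a subunit of cytochrome c oxidase, had 13.6 ± 5.26 CPM in WT and 13.3 ± 6.49 CPM in tls1 (SD, n = 3 each). The 5 mitochondrial ribosomal protein genes had a median of -0.12 and the 29 open reading frames of unnamed function a median of -0.07 (camera adjusted p = 0.847 and 0.838). The mitochondrial share varied more within a genotype than between them, from 0.187% to 0.319% in WT and from 0.135% to 0.316% in tls1. The libraries were enriched for poly-A RNA, so mitochondrial, plastid and non-coding reads need not measure the levels of those RNAs in the tissue.

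Plastid genes took 0.00233% ± 0.00087 of the reads in WT and 0.00215% ± 0.00093 in tls1 (SD, n = 3 each, exact permutation p = 1.0). Of 29 plastid genes tested, 0 were called with or without the block. Their levels were low, with WT means from 0.10 CPM for petB to 2.52 CPM for atpA. The SE of their log2 fold changes without the block ran from 0.35 for atpF to 0.89 for ndhC. In the same fit Zm00001d048841, with a log2 fold change of 4.33 ± 0.54 (SE), was not called. Even large changes of plastid genes could therefore have been missed. The 6 genes of the photosystems and the cytochrome b6f complex, which carry out the light reactions of photosynthesis, had a median log2 fold change of -0.09, and the 9 plastid ribosomal protein genes a median of -0.23 (camera adjusted p = 0.891 and 0.847). All 154 microRNA genes were listed at 0 in every library.

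Of the 264 tested non-coding RNA identifiers, 0 were called individually by edgeR with or without the block and 13 had an unadjusted p under 0.05 without it. As a group they were called lower in tls1 by camera (adjusted p = 0.0256), with a median log2 fold change of -0.13 and 172 of 264 negative. Their summed level was lower in tls1 only in pair 1, with 819 CPM in WT 1 and 625 in tls1 1. It was higher in tls1 in pair 2 (679 in WT, 756 in tls1) and pair 3 (664 in WT, 680 in tls1). The camera call was lost with an estimated correlation, which was 0.086 for this group (adjusted p = 0.958). With fry, which tests the group alone and not against the other genes, the adjusted p was 0.945. Their share of the reads was 0.0722% ± 0.0086 in WT and 0.0697% ± 0.0067 in tls1 (SD, n = 3 each, exact permutation p = 0.7). Adjusted over the list alone, 0 genes were called in each of the 8 groups. The number of groups that camera called went from 1 to 0 without WT 1 or tls1 1, to 4 without tls1 2 and to 2 without WT 3.

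**Figure D4:**
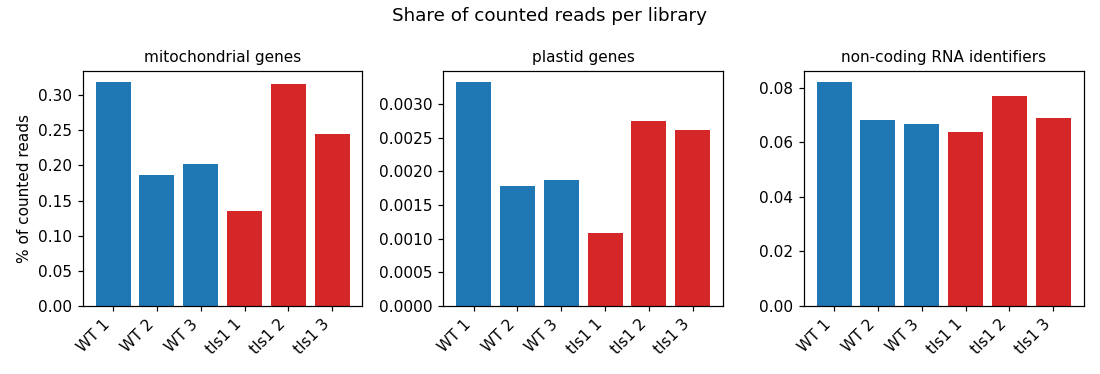
Percent of counted reads in mitochondrial genes, plastid genes and non-coding RNA identifiers, 1 bar per library, WT in blue and tls1 in red. In all 3 panels tls1 2 and tls1 3 lie above WT 2 and WT 3 but below WT 1, and tls1 1 is the lowest library, so the genotypes overlap.

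Along the row order of the nuclear genes, both libraries of 1 replicate number stood apart from the other 4 by at least 0.5 on the log2 scale in 294 genes for pair 1, 357 for pair 2 and 532 for pair 3. Such counts were not particular to a shared number. They were 612 for WT 1 with WT 3 and 480 for tls1 1 with tls1 2, and from 29 to 179 for the remaining combinations of different numbers. The tls1 libraries stood apart from the WT libraries by that much in 413 genes, 344 of them higher in tls1. In windows of 100 genes, the genes of the replicate pairs 1, 2 and 3 lay closer together than random placement gave. The fullest window held 23, 18 and 28 of them for pairs 1, 2 and 3, against at most 10, 12 and 16 in 10000 random placements. Pair 2 did not exceed the highest random placement in windows of 200 genes (18 against 19, permutation p = 0.0002). Nor did it at a log2 gap of 1 in windows of 100 genes (9 against 10, permutation p = 0.0004). The genes of the genotype comparison also lay closer together than most random placements: their fullest window held 11, where 95% of placements held at most 9 and the highest 13 (permutation p = 0.004).

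**Figure D5:**
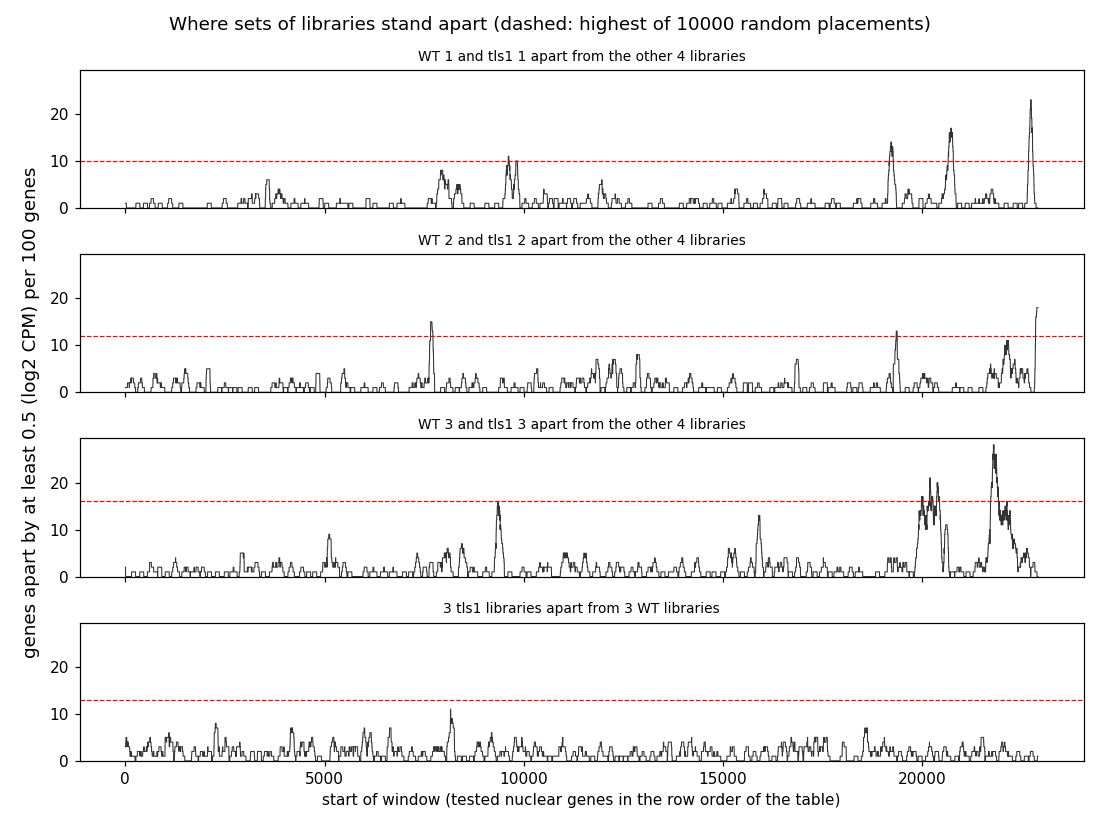
Genes per window of 100 consecutive tested nuclear genes in which a set of libraries stands apart from the rest by at least 0.5 (log2 CPM), against the start of the window in the row order of the table. The upper 3 panels show the replicate pairs, with fullest windows of 23, 18 and 28, the lowest panel shows tls1 against WT, with 11, and dashed lines are the highest of 10000 random placements.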

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

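Alternatives with DESeq2 and the block, robust empirical Bayes, the block without a pair and the removal of pair-block genes were chosen after seeing the data. The count of 1 gene higher and 0 lower was the same with RLE or upper quartile factors, the stricter filter, robust empirical Bayes and without the 10 most abundant genes. It was 13 higher and 0 lower with no filter, all 13 over 2-fold, and 2 higher with limma-voom, both over 2-fold. DESeq2 called 686 higher and 512 lower, 394 over 2-fold, and DESeq2 with the replicate block 899 and 741, 445 over 2-fold. The edgeR replicate block gave 115 and 47, 109 over 2-fold. The block without pair 1 gave 301 and 132, 195 over 2-fold, without pair 2 it gave 122 and 37, 128 over 2-fold, and without pair 3 it gave 43 and 9, 52 over 2-fold. Without the genes of pair blocks 13 were higher and 1 lower, 13 over 2-fold, and with the replicate block as well 107 and 43, 101 over 2-fold. Leaving out 1 library gave from 0 to 9 higher, from 0 to 1 lower and from 0 to 9 over 2-fold. Apart from the fewer libraries, the cause was not tested.

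The number of groups called was 1, from 0 to 4 without 1 library, 0 with an estimated correlation and 0 with fry. With the replicate block and 1 pair left out it was 7 without pair 1, 4 without pair 2 and 3 without pair 3. The block over all pairs left it at 1, and at an estimated correlation no group was called with it (adjusted p = 0.976). These counts use the preset correlation of 0.01, while the estimates for the organellar groups without the block ran from 0.643 to 0.911. For the non-coding RNA identifiers, the group called in the main fit, the estimate was 0.086. The fits without a pair were not run with an estimated correlation.

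The CPM of tls1 and WT libraries did not overlap in any printed gene, and every alternative reused these libraries, so a reversal was hardly possible. Each printed gene kept its direction in all 21 alternatives. Zm00001d005813 had log2 fold changes from 1.87 to 2.08 and missed the threshold in 5 of them, each with 1 library left out (highest adjusted p = 0.298). Zm00001d048841 ranged from 3.98 to 4.80 and passed in 7, Zm00001d012398 from -0.90 to -0.66 and passed in 6, and Zm00001d037717 from -1.20 to -0.63 and passed in 6. Every pass of Zm00001d048841, Zm00001d012398 and Zm00001d037717 came from DESeq2 or a fit with the block. They had been chosen for their low p in edgeR with the block, so passes in fits with the block are no independent support. The fullest window of genes called by edgeR with the block did not exceed chance at 100, 50 or 200 genes, while that of genes called by DESeq2 with the block did (permutation p = 0.0134, 0.0255 and 0.0174). That of genes called by DESeq2 without the block did as well (permutation p = 0.0066, 0.0245 and 0.0015). The lowest count of a printed gene was 328 in a library (Zm00001d048841 in WT 1), so counting error was small beside the spread between libraries for that gene.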

Other observations

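The shares of mitochondrial, plastid and non-coding reads moved together across the 6 libraries, whatever the genotype. Mitochondrial and plastid shares had Pearson's r = 0.962 (exact permutation p = 0.0028, adjusted 0.0056) and Spearman's rho = 1.0 (exact permutation p = 0.0028, adjusted 0.0056), with r = 0.994 without the 2 libraries farthest from the median mitochondrial share. Mitochondrial and non-coding shares had r = 0.934 (exact permutation p = 0.0083, adjusted 0.0083) and rho = 0.943 (exact permutation p = 0.0167, adjusted 0.0167), with r = 0.881 without those 2. These 2 relations were computed, and shares of 1 total are not independent measures. The permutations treated the 6 libraries as exchangeable and did not use the pairing by replicate number. In libraries enriched for poly-A RNA, such shares need not measure the levels of these RNAs in the tissue. Most mitochondrial reads came from the ribosomal RNAs rrn26 and rrn18. The summed level of the tested respiratory chain and ATP synthase genes ranked the 6 libraries as the mitochondrial share did, from 80.9 CPM in WT 1 to 28.8 CPM in tls1 1. The relations themselves were not computed for these genes.

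Of the tests that follow, only the exchange of genotype labels within pairs and the share of the split's calls in the blocks were set out before their results were seen. The window scan of called genes was planned before the data were examined. The others were chosen after.

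The first pattern was a run of neighbouring genes in which both libraries of 1 replicate number stood apart from the other 4 by at least 0.5 on the log2 scale. In pair 3 the fullest window of 100 genes, between zma-MIR399j and zma-MIR169r, held 28 such genes where 2.31 were expected and the highest of 10000 random placements held 16, which argues against chance placement. The highest windows of pairs 1 and 2 held 23 and 18 (highest random 10 and 12), although for pair 2 windows of 200 genes did not exceed the highest random placement. Among the more expressed genes the fullest windows of pairs 1 and 3 still held 7 and 9 (highest random 6 and 7), which argues against low counts there, while that of pair 2 held 4 (highest random 5), so low counts remain a candidate explanation for pair 2. Chromosome segments of another parent shared by the plants of one replicate number stay open: 0 of the 12 pairs of libraries with different numbers had a window above its highest random placement, but tls1 1 with tls1 3 reached it (8 against 8, permutation p = 0.0003), WT 1 with WT 2 had p = 0.0088, and the labels give no pedigree.

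The second pattern was a split that does not follow genotype and keeps pairs 2 and 3 whole, on opposite sides, while parting pair 1. WT 1, WT 3 and tls1 3 against the other 3 libraries gave 2221 DESeq2 calls, more than the 1198 between genotypes, so 2 of the 10 splits gave as many, which points to a structure of the samples. Among the 4 splits that part all 3 pairs, the highest other than the real one gave 7. Of the 3 libraries, 2 had mitochondrial shares inside the range of the other 3, which argues against the share of mitochondrial reads, and 8.73% of the split's calls lay in the pair blocks, which hold 8.03% of the genes given an adjusted p by DESeq2 in that split. No biological explanation was tested, since the design has no group that follows this split.

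The third pattern was the set of 162 genes called between genotypes with the replicate block. Exchanging the labels within a pair gave 0 calls in each of the other 3 arrangements, so 1 of 4 splits gave as many, and without the block the real split gave 1 call and the highest other 0 (1 of 10). Both sets of splits are too few for a share under 0.05. The fullest window of 100 genes held 5 of the 162 (permutation p = 0.486) and the fullest 1000 genes held 9.88% of them, which argues against a donor segment linked to the mutant allele as the source of most calls. In the gene order 9 called genes were directly followed by another, all 9 in the same direction and 8 with both higher, where random placement gave 1.12 on average and 6 at most (permutation p = 0.0001, the smallest these permutations can give), which argues against chance for neighbouring called genes, and reads shared between neighbouring copies of a gene were not tested.

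The DESeq2 calls with the block had a fullest window of 21 in 100 genes, between zma-MIR482 and zma-MIR166i (permutation p = 0.013, highest random 24). Of these 21, 4 were higher in tls1. The fullest edgeR window of 100 genes with the block lay between the same landmarks, with 0 of its 5 calls higher in tls1. The fullest 1000 genes held 6.67% of the DESeq2 calls with the block (permutation p = 0.0019) and 6.94% without it (permutation p = 0.0053). A donor segment as the source of some of the calls therefore stays open. Genes in which tls1 and WT stood apart by at least 0.5 numbered 413, of which 344 were higher in tls1, and their fullest window held 11, between zma-MIR156b and zma-MIR159f (permutation p = 0.004, highest random 13).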
